A study of Homo sapiens with 12 samples.

How the data were processed

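Gene expression was measured by RNA sequencing in 12 libraries of primary human small airway epithelial cells, 4 each with scrambled, JUP or PLEC siRNA at 50 nM for 72 h. Per the labels' protocols, libraries were made with a stranded messenger RNA kit (KAPA mRNA HyperPrep, dUTP). Per the submitters' processing notes, bcl2fastq 2.19.1.403, STAR, Partek and DESeq2 were used, without versions for the last 3 and without a statement of which tool made which value. The deposited values are expected counts per gene: 59.2% of them are whole within 0.001 and the rest are fractions. They were rounded to whole numbers before any fit. The notes name GENCODE release 29 and build hg38, and they do not say whether counting used the strand, so reads of overlapping genes on opposite strands cannot be told apart. Gene positions are those of the deposited file, with the end taken as the deposited stop less 1.

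Of 29816 gene entries, 22424 carried a name in the file, 7386 were named from a table of gene identifiers, and 6 had no symbol. All 12 columns matched a sample and 0 were left over. XIST, TSIX and Y-linked genes were left out of every table. Library totals ran from 46600201 to 68520493 counts. The 10 most abundant genes took 7.46 to 8.37% of counts and protein-coding genes 97.3 to 97.6%. Replicates of a group were not duplicates of each other (chi-square per gene 5.41 to 44.1 over their 18 pairs); libraries of different groups were not compared in this way.

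Genes were kept by filterByExpr in edgeR 4.0.16 (18362 genes). Libraries were scaled by trimmed mean of M values (TMM, factors 0.984 to 1.02). All 12 libraries entered 1 quasi-likelihood fit with group as the only term and 9 residual degrees of freedom. The 3 comparisons were each knockdown against scrambled and JUP against PLEC knockdown, with two-sided tests and Benjamini-Hochberg adjusted p below 0.05. The common biological coefficient of variation was 7.81%. Principal component 1 (16.0% of variance) was lowest in scrambled replicates 2 (-33.7) and 1 (-21.1), then in PLEC knockdown replicates 1 (-13.8) and 2 (-7.64). Component 2 (13.2%) set PLEC knockdown replicate 2 (-37.3) apart, with PLEC knockdown replicate 3 next (-15.0) and the other libraries at -7.77 or above.

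For 39 gene lists fixed before the data were examined, 863 of 901 genes were matched. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. No list call by camera at the preset correlation held with an estimated correlation, with all libraries or without the 3 of highest mitochondrial share. The targeted gene was left out of a list for its own knockdown, and both targets for the direct comparison. List members over all genes used the edgeR adjusted p, and counts adjusted over the list alone used the members only.

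The named genes followed a rule fixed before the data were examined. It took the target, then the 10 highest and 10 lowest log2 fold changes (8 and 8 for the direct comparison) among called genes with an average log2 CPM of at least 3, no overlap between the 4 libraries of either group, and a symbol that is not a clone name. It also took up to 4 members with the smallest p from each list described, and all desmosome and hemidesmosome members; not all of these are named. Outside the rule, INSIG1, COL7A1, COL6A1 and THBS1 are named in the list results of JUP knockdown, chosen after their values were seen. Of the 47 genes named by fold, 9 overlap another gene on the same strand, 23 overlap one on the opposite strand and 7 have annotated pseudogenes of their name, so part of their reads is uncertain.

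Alternatives were DESeq2 1.42.0, other scaling factors, no filter or a stricter filter (10 CPM in at least 4 libraries), limma voom with quality weights, fits of only the 8 libraries compared, the replicate number as a block, glmTreat against a 1.5-fold change, and 12 fits that each left out 1 library. A fit without the 3 libraries of highest mitochondrial share, camera with an estimated correlation in that fit, and a fit with that share as a covariate were added after seeing the data. The correlation of the knockdowns was set beside 20 simulations with shared controls, and 20 more in which libraries of the same number were tied at a correlation of 0.0793. To ask whether calls rest on the scrambled side, genes were picked with 2 libraries of a knockdown against scrambled siRNA and followed in its other 2 libraries against the other knockdown, over the 6 ways to choose the 2.

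Words of 7 bases were sought in annotated 3′ untranslated regions of at least 50 bases, which 13636 tested genes had (74.3%). A single transcript per gene was searched, so words in the gene's other transcripts were missed. A word was chosen on odd-numbered chromosomes (7390 genes) and tested on the others (6246 genes) with 1000 permutations. The word test is thus limited to that share of genes, and the other tested genes count as not searched.

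The methods were tested on simulated counts for 18362 genes with 200 changed. Each gene was drawn independently, without structure shared by the genes of a library, so the simulated shares of unchanged genes may not hold for the real calls. In the simulation of JUP knockdown against scrambled, edgeR recovered 71.6% of the 1.25-fold changes and 98.5% of the 1.5-fold and of the 2-fold changes, and 6.77% of its calls were unchanged genes. For PLEC knockdown it recovered 71.6%, 100% and 100%, with 3.72% unchanged among the calls. DESeq2 had 14.9% and 15.6% unchanged genes among its calls. A planted word was found in 5 of 5 simulations at a shift of -0.25, and in 0 of 5 with no shift. With 200 of 18362 genes changed on the scrambled side alone, the picked genes went the same way in 46.3% for PLEC and 45.6% for JUP knockdown, and with the change in the knockdown in 97.2% and 97.8%. Software was Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9) and R 4.3.3.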

Results

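Messenger RNA was sequenced from primary human small airway epithelial cells that had been electroporated with small interfering RNA (siRNA). The siRNA targeted JUP (plakoglobin, an armadillo protein of desmosomes and adherens junctions), PLEC (plectin, which links keratin filaments to hemidesmosomes) or, as the control, had a scrambled sequence. The siRNA dose was 50 nM and cells were collected after 72 h. Each of the 3 groups had 4 libraries, 12 in all. The labels number the replicates and do not say that they were separate cultures, so the p-values measure a spread between samples that may be technical. Library totals ranged from 46600201 to 68520493 counts. They were 65741054, 58806772, 55044394 and 64432453 in scrambled replicates 1 to 4, 68520493, 53826460, 58746617 and 54898841 in JUP knockdown replicates 1 to 4, and 54090762, 46600201, 50297066 and 50490888 in PLEC knockdown replicates 1 to 4. Transcripts encoded by the mitochondrial genome took 7.01% of counts in scrambled replicate 2, 6.53% in PLEC knockdown replicate 1 and 6.49% in scrambled replicate 1, against 5.32 to 5.71% in the other 9 libraries. Values are CPM (counts scaled to a common library total) with the standard deviation (SD) over n = 4 libraries, and log2 fold changes with their standard error (SE) from edgeR. Positions are on genome build hg38.

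Both knockdowns lowered their own target in every library, and neither lowered the other target. JUP (ENSG00000173801, chromosome 17, 41754604 to 41786931) had 652 ± 45.1 CPM (SD, n = 4) in the scrambled group and 38.1 ± 9.76 CPM (SD, n = 4) in JUP knockdown, where 5.85% of the scrambled level remained (4.22 to 7.64% in single libraries). Its log2 fold change was -4.10 (SE 0.14, edgeR adjusted p = 1.5e-10). PLEC (ENSG00000178209, chromosome 8, 143915153 to 143976734) had 1894 ± 215 CPM in the scrambled group and 501 ± 50.5 CPM in PLEC knockdown, where 26.5% remained (22.6 to 28.5%). Its log2 fold change was -1.92 (SE 0.08, edgeR adjusted p = 5.4e-09). JUP had 692 ± 22 CPM in PLEC knockdown (log2 fold change 0.09, SE 0.12, edgeR adjusted p = 0.79) and PLEC had 1928 ± 96.7 CPM in JUP knockdown (0.03, SE 0.08, edgeR adjusted p = 0.888).

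**Figure D1:**
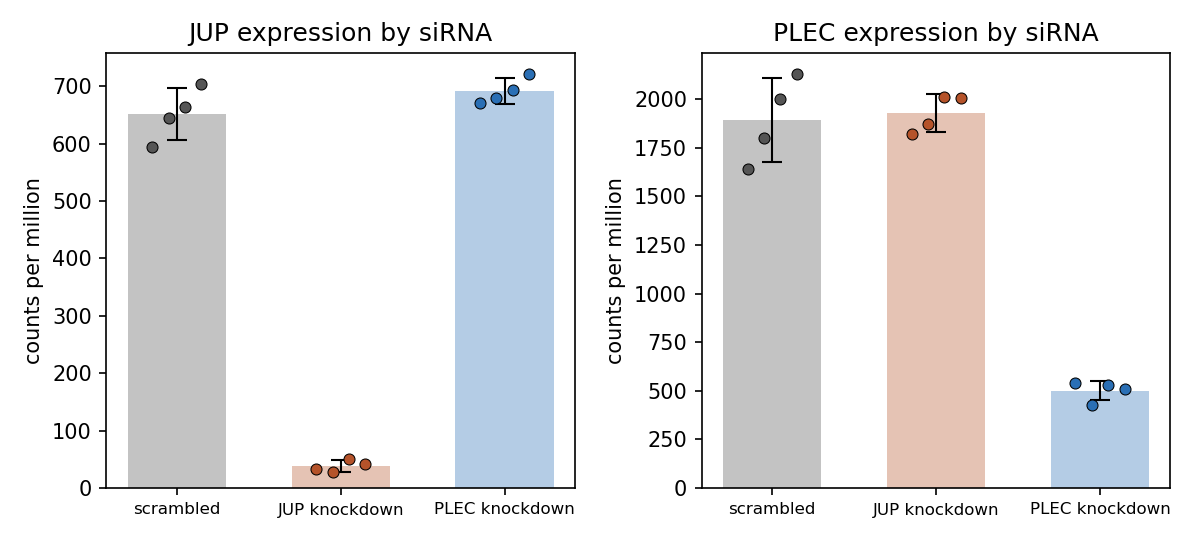
JUP and PLEC levels (CPM, y axis) in the 3 groups (x axis), with bars for the mean of 4 libraries, error bars for the SD and points for single libraries. JUP knockdown libraries lie between 27.5 and 49.8 CPM for JUP, and PLEC knockdown libraries between 428 and 541 CPM for PLEC.

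The comparison of JUP knockdown with scrambled siRNA asked which transcripts differ when plakoglobin mRNA is reduced. Among the genes that fell were PGM2L1 (a sugar phosphate enzyme), CDC42 (a Rho-family GTPase of cell polarity), MSI2 (an RNA-binding protein) and DAZAP2. Several enzymes of cholesterol synthesis, such as MVD and FDPS, and the collagens COL1A1 and COL5A1 were among the genes that rose. Decreases outnumbered increases: 64 genes were higher and 212 lower of 18362 tested, and the median change of the called genes was 1.25-fold. PGM2L1 (ENSG00000165434, chromosome 11, 74330316 to 74398433) fell from 72.0 ± 7.11 to 39.6 ± 5.77 CPM (log2 fold change -0.86, SE 0.09, edgeR adjusted p = 0.00038). CDC42 (ENSG00000070831, chromosome 1, 22052627 to 22101360) fell from 234 ± 3.87 to 136 ± 18.5 CPM (-0.79, SE 0.07, edgeR adjusted p = 0.00011), though 6 pseudogenes carry its name and could share its reads. MSI2 (ENSG00000153944, chromosome 17, 57255851 to 57684689) fell from 49.7 ± 1.23 to 28.9 ± 4.6 CPM (-0.78, SE 0.08, edgeR adjusted p = 0.00033). DAZAP2 fell from 176 ± 11.9 to 115 ± 10.5 CPM (-0.61, SE 0.06, edgeR adjusted p = 0.0002). The rest of the 10 lowest were SCML1 (-0.79), the transcription factors IKZF2 (-0.63) and TEF (-0.59), EREG (-0.59), which encodes the growth factor epiregulin, NPIPB13 (-0.58), a member of a multigene family, and SLC7A11 (-0.58), a cystine transporter. The 10 highest began with CAVIN3 (0.59), a caveola protein, PCSK9 (0.53), which lowers the LDL receptor, and COL1A1 (0.49), which rose from 195 ± 12.7 to 273 ± 26.5 CPM (edgeR adjusted p = 0.0174). They went on with CRIP2 (0.47), AMDHD2 (0.46), MVD (0.46), the glucose transporter SLC2A3 (0.46), COL5A1 (0.45), the calcium channel ORAI3 (0.41) and ARHGEF40 (0.39). The rule that named these 20 genes required the 4 libraries of each group not to overlap. That held for 261 of the 276 called genes and for 9.88% of all tested genes, where chance gives 2.86%.

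Without scrambled replicate 4, edgeR called 1035 genes higher and 1021 lower; without JUP knockdown replicate 1 it called 0 higher and 19 lower (1276 higher and 1396 lower at an unadjusted p under 0.05). There were 26, 37 and 41 higher genes without JUP knockdown replicates 3 and 4 and PLEC knockdown replicate 2, and the sum of both directions was 76, 95 and 99 without scrambled replicates 1, 2 and 3, 41 without JUP knockdown replicate 2, and 170 and 164 without PLEC knockdown replicates 3 and 4, which enter through the shared spread. PGM2L1, CDC42, MSI2, IKZF2 and DAZAP2 kept their calls in all 12 fits that left out 1 library, and none of the 10 highest genes did. A fit without the 3 libraries of highest mitochondrial share, chosen after seeing the data, called 11 genes higher and 28 lower. There, 6 of the 10 lowest genes were called (PGM2L1, CDC42, MSI2, IKZF2, DAZAP2 and SLC7A11) and 1 of the 10 highest (SLC2A3).

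Among gene lists fixed beforehand, cholesterol synthesis stood out in JUP knockdown. Of its 24 measured genes 8 rose and 1 fell, or 18 and 1 adjusted over the list alone, and 15 did not pass over all genes. HSD17B7 (a hydroxysteroid dehydrogenase) had a log2 fold change of 0.24, FDFT1 (squalene synthase) 0.20, FDPS (farnesyl diphosphate synthase) 0.32 and PCSK9 0.53, while INSIG1 fell (-0.36, SE 0.08, edgeR adjusted p = 0.0464). The list was higher by camera (camera adjusted p = 1.7e-10; adjusted p = 0.612 with an estimated correlation; fry adjusted p = 0.0332), and it stayed higher without the 3 high-mitochondrial libraries (camera adjusted p = 1.1e-15; adjusted p = 0.516 with an estimated correlation), although no single member was then called. Of 28 hypoxia and glycolysis genes 3 rose and 0 fell (5 and 0 adjusted over the list alone): SLC2A3, CA9 (0.57), a carbonic anhydrase, and ALDOC (0.35), an aldolase. That list's camera adjusted p was 0.00016 (adjusted p = 0.826 with an estimated correlation). Without the 3 high-mitochondrial libraries SLC2A3 alone was called, and the camera adjusted p was 0.0492 (adjusted p = 0.619 with an estimated correlation). Of 29 collagen and matrix genes 4 rose and 3 fell (9 and 3 adjusted over the list alone); COL1A1, COL5A1, COL7A1 (0.37) and COL6A1 (0.30) rose, and COL12A1 (-0.38), FBN2 (-0.35) and THBS1 (-0.25) fell. The camera adjusted p was 0.0050 (adjusted p = 0.826 with an estimated correlation). Without the 3 high-mitochondrial libraries 0 members rose and 0 fell, while the list was higher by camera (adjusted p = 0.0131, or 0.538 with an estimated correlation). COL1A1 was also the 1 gene that rose of 12 fibroblast markers, a list with a camera adjusted p of 0.145. Of 23 YAP/TAZ targets 0 rose and 2 fell (0 and 4 adjusted over the list alone): CCN2 (-0.49, SE 0.08, edgeR adjusted p = 0.0086) and TGFB2 (-0.56, SE 0.13, edgeR adjusted p = 0.0482). That list was lower by camera (adjusted p = 0.0032; adjusted p = 0.612 with an estimated correlation). CCN2 was not called without JUP knockdown replicate 1 (edgeR adjusted p = 0.0511), and TGFB2 was not called in 9 of the 12 fits that left out 1 library. Neither was called without the 3 high-mitochondrial libraries.

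More camera calls came without a member called by edgeR over all genes. The 42 ribosomal protein genes (median log2 fold change 0.07, camera adjusted p = 0.00016; adjusted p = 0.826 with an estimated correlation) had 9 members higher at an unadjusted p under 0.05 and 1 called by DESeq2. The 26 p53 targets (median 0.11, camera adjusted p = 0.0050; adjusted p = 0.826 with an estimated correlation) had 10 higher and 1 lower at an unadjusted p under 0.05, and 2 higher and 1 lower by DESeq2. The 13 mitochondrial-encoded transcripts were lower (median -0.18, camera adjusted p = 0.0016; adjusted p = 0.826 with an estimated correlation), with 3 lower at an unadjusted p under 0.05 and none by DESeq2. Scrambled replicates 1 and 2 carried 2 of the 3 highest mitochondrial shares. Without those 3 libraries the mitochondrial list had the opposite direction (camera adjusted p = 0.675), and neither the ribosomal list (0.295) nor the p53 list (0.187) was called.

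The comparison of PLEC knockdown with scrambled siRNA asked the same of plectin. The collagenase MMP1, the stromelysin MMP10 and the plasminogen activator inhibitor SERPINE1 fell, 3 of the 26 matrix proteases and inhibitors measured. HAS3, a hyaluronan synthase, and the chemokine CXCL14 rose. In total 99 genes were higher and 191 lower of 18362 tested, again with a median change of 1.25-fold among the called genes. MMP1 (ENSG00000196611, chromosome 11, 102789401 to 102798160) fell from 14 ± 1.04 to 7.51 ± 0.957 CPM (log2 fold change -0.89, SE 0.13, edgeR adjusted p = 0.0041). INSIG1 (ENSG00000186480, chromosome 7, 155297776 to 155310235) fell from 118 ± 4.78 to 75.4 ± 8.77 CPM (-0.64, SE 0.09, edgeR adjusted p = 0.0041). VDAC2, a channel of the mitochondrial outer membrane, fell from 215 ± 8.64 to 135 ± 34.5 CPM (-0.67, SE 0.13, edgeR adjusted p = 0.0211), with 4 pseudogenes of its name. The other 7 of the 10 lowest were DDAH1 (-0.82), which breaks down methylarginines, the receptor EPHA1 (-0.77), the kinases AKT3 (-0.69) and MAPK6 (-0.59), ZNF721 (-0.66), TMEM65 (-0.59) and ERLIN2 (-0.58). HAS3 (ENSG00000103044, chromosome 16, 69105653 to 69118719) rose from 108 ± 9.85 to 163 ± 16.6 CPM (0.59, SE 0.07, edgeR adjusted p = 0.0033). CXCL14 rose from 9.24 ± 0.902 to 12.8 ± 0.900 CPM (0.47, SE 0.08, edgeR adjusted p = 0.00997). Among genes that met the naming rule, the highest folds belonged to RN7SL1 (2.10, SE 0.43, edgeR adjusted p = 0.026) and RN7SL2 (1.90, edgeR adjusted p = 0.0482). These are near-identical genes for the RNA of the signal recognition particle, and their reads cannot be assigned with certainty. Neither kept its call in all 12 fits that left out 1 library. RN7SL2 also varied within JUP knockdown, at 5.46 CPM in replicate 1 against 16.7 to 18.9 CPM in the others. CPA4 (0.46), the myosin light chain MYL9 (0.43), PSAT1 (0.43), an enzyme of serine synthesis, PRRG4 (0.40), SESN3 (0.38) and NACC2 (0.38) completed the 10 highest. The 4 PLEC knockdown libraries lay on one side of all 4 scrambled libraries for 276 of the 290 called genes, and for 7.52% of all tested genes against 2.86% by chance.

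The sum of both directions was 54, 75 and 89 without PLEC knockdown replicates 4, 2 and 3, 93, 141 and 135 without scrambled replicates 1, 2 and 3, 514 without scrambled replicate 4 and 516 without PLEC knockdown replicate 1; without JUP knockdown replicates 1, 2, 3 and 4 it was 180, 192, 177 and 192. MMP1, EPHA1, AKT3, ZNF721, INSIG1, TMEM65, ERLIN2, HAS3 and CXCL14 kept their calls in all 12 such fits. Without the 3 libraries of highest mitochondrial share, a choice made after seeing the data, 57 genes were higher and 134 lower. In that fit 9 of the 10 lowest genes were called, all but DDAH1, and 6 of the 10 highest (RN7SL1, RN7SL2, HAS3, CXCL14, PSAT1 and NACC2).

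Of 26 matrix proteases and inhibitors 0 rose and 3 fell in PLEC knockdown (1 and 6 adjusted over the list alone): MMP1, MMP10 (-0.57, SE 0.08, edgeR adjusted p = 0.0041) and SERPINE1 (-0.45, SE 0.07, edgeR adjusted p = 0.00997). Of these, MMP1 and MMP10 break down matrix and SERPINE1 restrains plasminogen activation. The list was lower by camera (adjusted p = 0.0026; adjusted p = 0.488 with an estimated correlation; fry adjusted p = 0.0554). Without the 3 libraries of highest mitochondrial share edgeR called 0 of its members higher and 2 lower, MMP1 among them. Of 26 p53 targets 3 rose and 0 fell (9 and 0 adjusted over the list alone): SESN1 (0.34), the antiproliferative gene BTG2 (0.32) and TP53 itself (0.31, SE 0.05, edgeR adjusted p = 0.0119). Its camera adjusted p was 2.2e-08 (adjusted p = 0.488 with an estimated correlation). TP53 was not called without PLEC knockdown replicate 4 (edgeR adjusted p = 0.0506). Of 42 ribosomal protein genes 1 rose, RPS27 (0.14), and 0 fell (29 and 0 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 4.4e-18; adjusted p = 0.488 with an estimated correlation); such genes have many pseudogenes. Of 25 NRF2 targets of the oxidative stress response 0 rose and 1 fell, the quinone reductase NQO1 (-0.46), or 0 and 6 adjusted over the list alone (camera adjusted p = 0.00011; adjusted p = 0.818 with an estimated correlation). Of 31 AP-1 and immediate early genes 0 rose and 1 fell, the growth factor TGFA (-0.43), or 0 and 8 adjusted over the list alone (camera adjusted p = 0.0011; adjusted p = 0.706 with an estimated correlation). The 13 mitochondrial-encoded transcripts were lower in PLEC knockdown (median -0.20, camera adjusted p = 0.00057; adjusted p = 0.855 with an estimated correlation), with 3 lower at an unadjusted p under 0.05 and 0 called by edgeR or DESeq2. Without the 3 high-mitochondrial libraries these lists kept their direction, with camera adjusted p = 0.0021 for proteases, 2.5e-07 for p53 targets, 2.4e-10 for ribosomal proteins, 1.1e-11 for NRF2 targets, 0.00071 for AP-1 genes and 0.0035 for mitochondrial-encoded transcripts; with an estimated correlation these were 0.473, 0.091, 0.765, 0.473, 0.765 and 0.804.

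**Figure D2:**
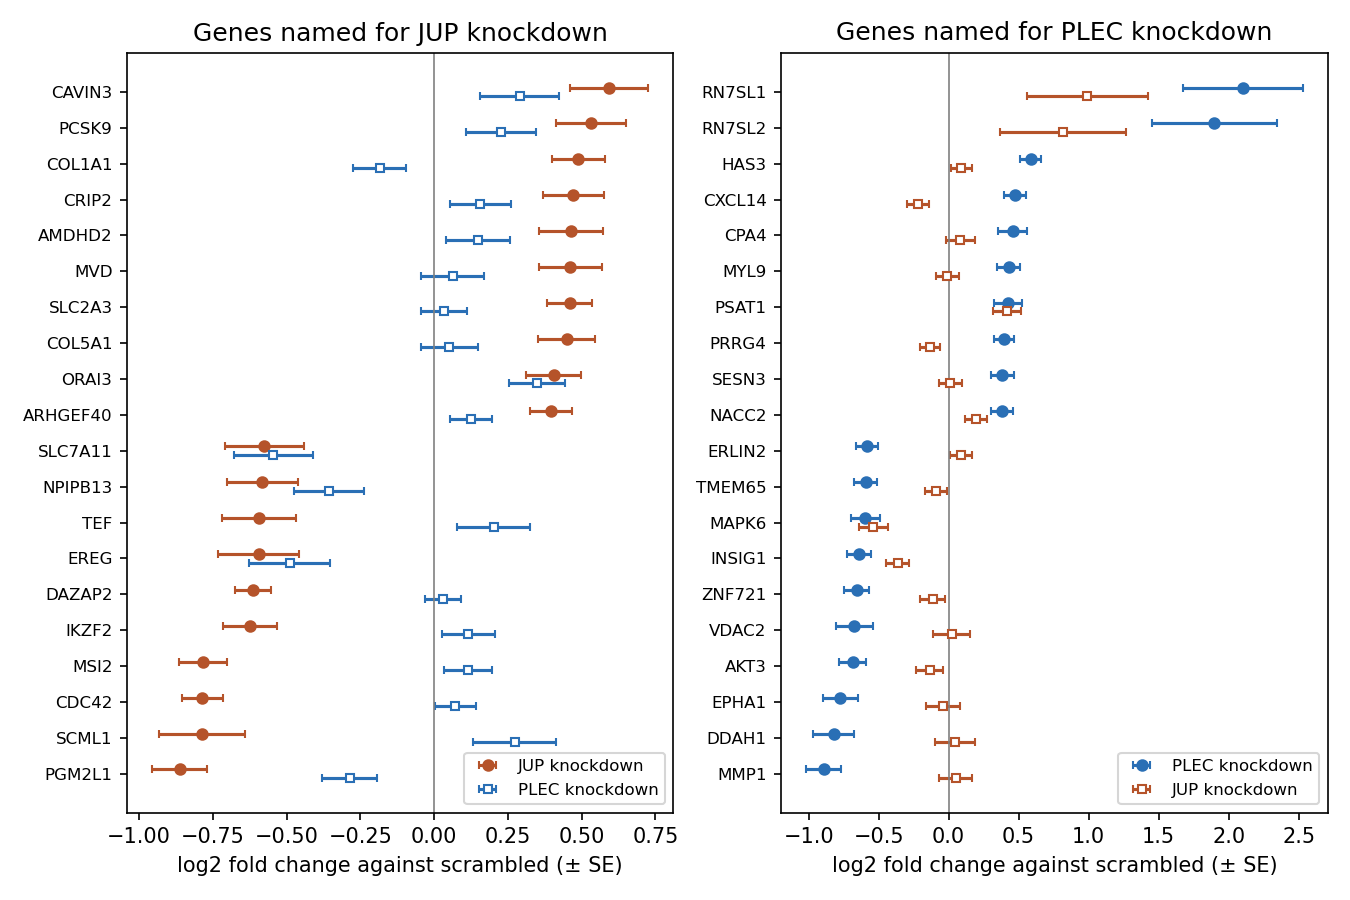
Log2 fold changes against scrambled siRNA (x axis) of the 20 named genes of each knockdown (y axis), with the SE as error bars, filled points for the knockdown that named the gene and open squares for the other knockdown. CDC42 has -0.79 in JUP knockdown, and MMP1 has -0.89 in PLEC knockdown.

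Few junction genes other than the targets were called against scrambled siRNA. Of 9 other desmosome genes, edgeR called 0 in JUP knockdown (1 higher and 3 lower at an unadjusted p under 0.05, and 0 by DESeq2). DSP (desmoplakin) had -0.16 (SE 0.07), DSG3 (desmoglein) -0.17 (SE 0.06), PKP2 (plakophilin) -0.14 (SE 0.06) and PKP3 0.26 (SE 0.09); the list had a camera adjusted p of 0.139. That p was 0.0456, in the lower direction, without the 3 high-mitochondrial libraries (adjusted p = 0.538 with an estimated correlation). In PLEC knockdown 1 of 10 desmosome genes fell, PERP (-0.44, SE 0.07, edgeR adjusted p = 0.00997), a tetraspan membrane protein, and the list had a camera adjusted p of 0.712. Of 8 hemidesmosome and laminin genes 1 fell in PLEC knockdown, LAMA3 (-0.23, SE 0.05, edgeR adjusted p = 0.0382), or 2 adjusted over the list alone with LAMC2 (-0.14); the camera adjusted p was 0.330. LAMA3 was called in 1 of the 12 fits that left out 1 library, the one without scrambled replicate 4. In JUP knockdown 0 of 9 hemidesmosome genes were called by edgeR (1 higher and 1 lower adjusted over the list alone, and by DESeq2; 2 higher and 2 lower at an unadjusted p under 0.05), with a camera adjusted p of 0.822. Of 16 keratins edgeR called 0 in either knockdown against scrambled siRNA. At an unadjusted p under 0.05 there were 1 higher and 1 lower keratin in JUP knockdown and 2 higher and 4 lower in PLEC knockdown, and DESeq2 called 0 and 1. The direct comparison did call junction genes: in JUP relative to PLEC knockdown PERP (0.38), LAMC2 (0.20) and the keratin KRT19 (0.18, edgeR adjusted p = 0.0286) were higher, and DSG3 (-0.24), DST (-0.25) and KRT17 (-0.13, edgeR adjusted p = 0.0467) were lower. Of 14 tight junction genes 2 were lower there, MARVELD3 (-0.33, SE 0.07, edgeR adjusted p = 0.0132) and CLDN1 (-0.32, SE 0.07, edgeR adjusted p = 0.0181), and 0 higher, as many as adjusted over the list alone. The camera adjusted p of that list was 0.0634, and 0.0217 with the replicate number as a block. Without the 3 high-mitochondrial libraries it was 0.0203 (adjusted p = 0.634 with an estimated correlation), and 3 members were lower there.

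The direct comparison of the knockdowns asked where the responses differed from each other, without scrambled libraries in the contrast. With all 12 libraries it gave the most calls, with 315 genes higher and 454 lower in JUP than in PLEC knockdown and a median change of 1.23-fold. SERPINE1 had 1187 ± 62.2 CPM in JUP knockdown and 736 ± 94.0 CPM in PLEC knockdown, with 1006 ± 48.6 CPM in the scrambled group (log2 fold change 0.69, SE 0.07, edgeR adjusted p = 0.00022); it was not called in JUP knockdown against scrambled siRNA (0.24, edgeR adjusted p = 0.108). Beside MMP1 (0.94, SE 0.13, edgeR adjusted p = 0.00092), the heme oxygenase HMOX1 (0.94, SE 0.15, edgeR adjusted p = 0.0029) and COL1A1 (0.67, SE 0.09, edgeR adjusted p = 0.00092) were higher in JUP knockdown. DDAH1 (0.86), the lysosomal transporter SPNS1 (0.78), EPHA1 (0.73) and VDAC2 (0.70) completed the 8 highest among genes that met the naming rule. The 8 lowest by that rule were SCML1 (-1.06), MSI2 (-0.90), CDC42 (-0.86, SE 0.07, edgeR adjusted p = 2.3e-05), TEF (-0.80), IKZF2 (-0.74), the interferon-induced GTPase GBP1 (-0.71), CXCL14 (-0.69) and the nucleotide receptor P2RY1 (-0.67). The libraries of the knockdowns were separated for 745 of the 769 called genes, and for 14.3% of tested genes against 2.86% by chance. All 16 genes kept their calls in the 12 fits that left out 1 library. Without scrambled replicate 4 it had 992 calls, fewer than the 2056 of JUP knockdown against scrambled siRNA. Leaving out JUP knockdown replicate 1 gave 133 higher and 177 lower; without JUP knockdown replicate 2, PLEC knockdown replicate 2 and PLEC knockdown replicate 4 the sums were 339, 372 and 512. Without the 3 high-mitochondrial libraries 561 were higher and 651 lower.

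Some matrix, hypoxia and cholesterol genes were called between the knockdowns, most members of each list were not, and no camera call of these lists held with an estimated correlation. Of 26 matrix proteases and inhibitors 5 were higher in JUP than in PLEC knockdown and 0 lower (6 and 1 adjusted over the list alone), with MMP9 at 0.95 and MMP10 at 0.62 (camera adjusted p = 0.00039; adjusted p = 0.244 with an estimated correlation). Of 28 hypoxia and glycolysis genes 8 were higher and 0 lower, and as many adjusted over the list alone, among them VEGFA (0.40), SLC2A3 (0.42), PFKFB4 (0.39) and PGK1 (0.34), with a camera adjusted p of 4.5e-07 (adjusted p = 0.428 with an estimated correlation). Of 24 cholesterol synthesis genes 4 were higher and 0 lower (8 and 0 adjusted over the list alone): MVD (0.40), SQLE (0.30), FDPS (0.29) and IDI1 (0.19). That camera adjusted p was 2.2e-06 (adjusted p = 0.428 with an estimated correlation). Of 29 collagen and matrix genes 4 were higher and 0 lower (5 and 1 adjusted over the list alone): COL1A1, COL4A1 (0.67), COL7A1 (0.47) and COL5A1 (0.40), with a camera adjusted p of 0.0482 (adjusted p = 0.712 with an estimated correlation). Of 23 YAP/TAZ targets 1 was higher and 4 lower (3 and 9 adjusted over the list alone), with CCN2 at -0.50 (camera adjusted p = 0.0073; adjusted p = 0.428 with an estimated correlation). Smaller camera calls were higher mesenchymal genes (1 higher and 1 lower of 19, adjusted p = 0.0194; adjusted p = 0.428 with an estimated correlation), higher stress response genes (2 and 0 of 25 with TRIB3 at 0.43, adjusted p = 0.0194; adjusted p = 0.578 with an estimated correlation) and higher NRF2 targets (HMOX1 alone of 25, adjusted p = 0.0316; adjusted p = 0.712 with an estimated correlation). The 42 ribosomal protein genes were lower by camera (median -0.07, adjusted p = 0.0016; adjusted p = 0.712 with an estimated correlation), with 13 lower at an unadjusted p under 0.05, 7 lower by DESeq2 and 0 by edgeR. The mitochondrial-encoded list had a median of -0.01 (camera adjusted p = 0.918), and without the 3 high-mitochondrial libraries it was higher in JUP knockdown (camera adjusted p = 0.00159; adjusted p = 0.682 with an estimated correlation). Without those libraries the collagen (0.490) and mesenchymal (0.386) lists were not called.

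**Figure D3:**
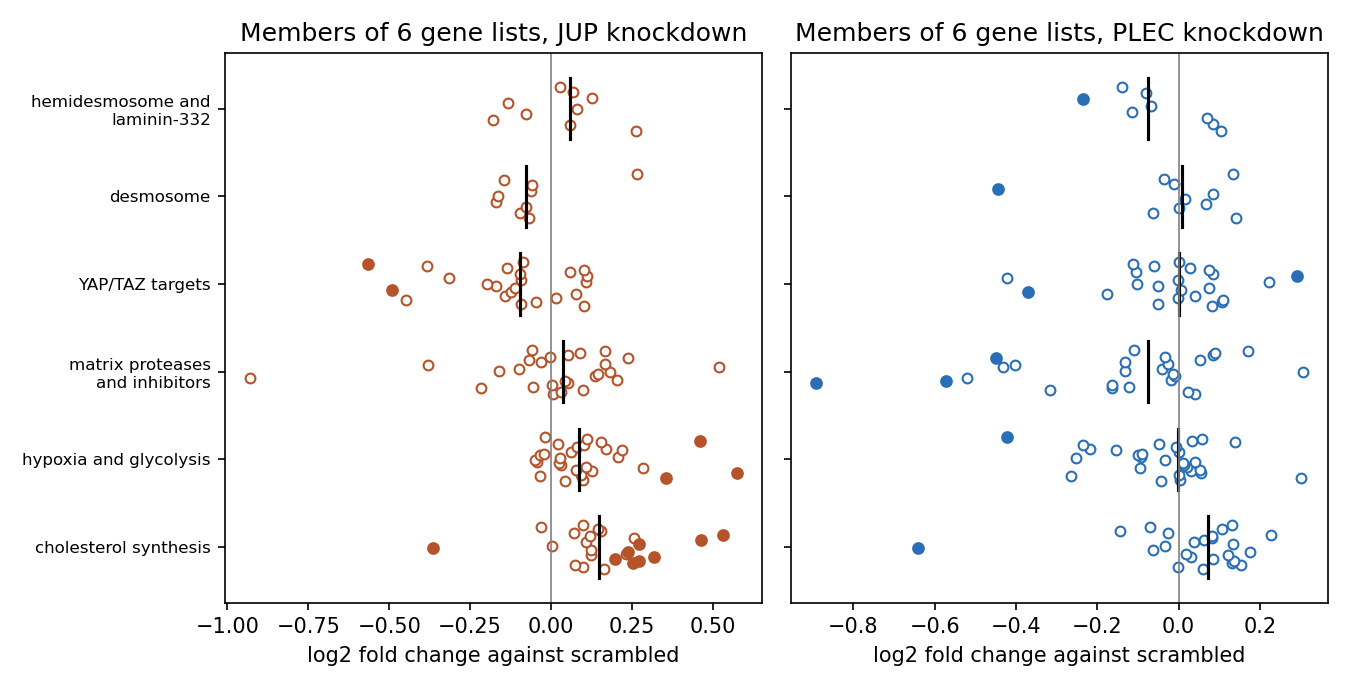
Log2 fold changes against scrambled siRNA (x axis) of the members of 6 gene lists (y axis) in both knockdowns, with filled points for members at an edgeR adjusted p below 0.05 and a vertical line at the list's median. Cholesterol synthesis genes have a median of 0.15 in JUP knockdown and 0.07 in PLEC knockdown.

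With all 12 libraries, markers of other cell types gave no camera call. Of 12 fibroblast markers the direct comparison had COL1A1 higher and MFAP5 (-0.29) lower (camera adjusted p = 0.332). Of 6 endothelial, 6 leukocyte and 11 alveolar epithelial markers edgeR called 0 in the 3 comparisons. At an unadjusted p under 0.05 the endothelial list had 1 higher in JUP knockdown and 1 lower in the direct comparison, the leukocyte list 1 higher in the direct comparison, and the alveolar list 1 lower in each knockdown and 2 lower in the direct comparison; DESeq2 called 0 of them. Of the airway lists, the 10 secretory and goblet cell genes had a camera adjusted p of 0.776 in PLEC knockdown, and were lower by camera without the 3 high-mitochondrial libraries (adjusted p = 0.0102; adjusted p = 0.591 with an estimated correlation), with 0 members called by edgeR in either fit and, with all libraries, 0 at an unadjusted p under 0.05 or by DESeq2. Of 15 basal cell genes TP63 (-0.18) and of 11 ciliated cell genes RFX3 (-0.34) were lower in the direct comparison (camera adjusted p = 0.716 and 0.724).

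The fold changes of the knockdowns were set against each other across the 18362 genes, which are not independent replicates. Pearson's r was 0.484, and it averaged 0.486 (0.467 to 0.506) over 20 simulations of unchanged groups that shared the 4 scrambled libraries. The covariance was 0.0314 against a simulated 0.0218, a difference of 0.00959. With the scrambled libraries split between the knockdowns the mean r was 0.0818 (-0.0167 to 0.128 over the splits), and the highest simulated mean was 0.026. Called in both knockdowns were 6 genes higher and 10 lower, where independent lists of these sizes would share 0.345 and 2.21. The simulations called at most 2 genes in a comparison and direction, so they give no level for this overlap. Leaving out JUP knockdown replicate 1 gave 0 shared genes in each direction by edgeR, and leaving out scrambled replicate 4 gave 69 and 111; DESeq2 with all libraries gave 55 and 71.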

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

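Of the tests here, the families of words taken from the ranked 7-base words, the 6-base cores, the genes picked with 2 libraries and followed in the others, the simulations with a tie between same-numbered libraries and the fits that use the mitochondrial share were chosen after a result was seen. In 147 sets of 4 libraries, 9 had a library far from the other 3 by the ratio of its gap to the whole range, where chance at 1 in 20 gives 7.35.

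PLEC knockdown replicate 1 had a mitochondrial share of 6.53% against 5.36 to 5.40% in the other 3 (ratio 0.966). EREG was 32.7 CPM in scrambled replicate 1 against 21.8 to 23.1 (ratio 0.884), and SLC7A11 was 271 CPM there against 183 to 193 (ratio 0.887). CRIP2 was 23.7 CPM in JUP knockdown replicate 4 against 27.3 to 27.9 (ratio 0.845). IKZF2 was 11.8 CPM in PLEC knockdown replicate 2 against 12.7 to 12.9 (ratio 0.870). INSIG1 was 109 CPM in JUP knockdown replicate 3 against 84.0 to 87.6 (ratio 0.855). MMP1 was 19 CPM in JUP knockdown replicate 2 against 12.4 to 13.5 (ratio 0.834). NACC2 was 44.6 CPM in PLEC knockdown replicate 1 against 55 to 57.0 (ratio 0.833). RN7SL2 was 5.46 CPM in JUP knockdown replicate 1 against 16.7 to 18.9 (ratio 0.833).

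The first pattern is the 212 genes lower in JUP knockdown, of which 197 had a searchable 3′ untranslated region. The word most tied to lower expression on odd-numbered chromosomes, ATGGCAT, also ranked 1 of 16384 on the others (permutation p = 0.000999, the smallest 1000 permutations give). There 47.9% of 94 called lower genes carried it, against 11.7% of the other genes. Called lower genes have longer 3′ untranslated regions (median 2294 bases against 1111 of all), and over all chromosomes 46.7% of the 197 carried it against 18.4% of genes of matched length. This fits silencing of other transcripts through the seed of the siRNA. The JUP lead words ATGGCAT and CAGACTA are both in JUP transcripts (2 of 2, chance 0.0428 if all 7-base words are equally likely), each in 3 of 10. They are also in 10 and 9 PLEC transcripts, so their presence says little about the target. CAGACTA was picked from a ranking over all genes, the called ones among them, so its excess in called genes is partly built in. Once the trend with GC content and length was removed, 100% of the genes stayed below 0 by more than 1 SE, a low bar for genes already called. The trend had a median of -0.054 in these genes, against a median log2 fold change of -0.310. Its size argues against GC content and length as the whole cause. Such off-target silencing may thus account for part of the lower genes. Of the 10 lowest, 6 carry a JUP lead word (PGM2L1, SCML1, MSI2, DAZAP2, EREG and SLC7A11), as does INSIG1, and these are candidates for it, although 6 of 10 is near the 55.3% of all called lower genes with either word (26% of genes of matched length). An effect of plakoglobin loss is not excluded for any of these genes, nor for the 88 without either word, CDC42 and CCN2 among them. Those 88 may still hold a seed match, since a single transcript per gene was searched. The shifted words TGGCATA and TATGGCA, ranked 2 and 3 over all genes, were not counted. The siRNA sequences are not known.

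The second pattern is the 191 genes lower in PLEC knockdown, 176 of them searchable. GGAATAA, chosen on odd-numbered chromosomes, ranked 1 on the others (permutation p = 0.000999, the smallest 1000 permutations give). There 38.1% of 84 called lower genes carried it, against 13.7% of the other genes. Over all chromosomes 38.1% of the 176 carried it against 18.9% of genes with 3′ untranslated regions of matched length. Once the GC and length trend was removed, 100% stayed below 0 by more than 1 SE, again a low bar for called genes. The trend had a median of -0.0095 in these genes against a median log2 fold change of -0.336. Its size argues against that trend as the whole cause. Of the 3 lead words GGAATAA, GGAGAAA and GATGATC, 0 are in PLEC transcripts, which goes against siRNA strands that pair with PLEC over the whole word. The reverse complements of the words were not searched, so nothing is shown for the opposite strand of such siRNAs. A core of 6 bases from each word is in PLEC transcripts, as are 67.9% of all 6-base words, so the cores decide nothing. GGAGAAA and GATGATC were picked from a ranking over all genes, the called ones among them, so their excess in called genes is partly built in. The shifted words AGGAGAA and AGGAATA ranked 3 and 5 in it and were not counted. A gene without a lead word may thus still hold a seed match. Off-target silencing may account for part of these genes. Of the 10 lowest, all 9 that were searched carry a lead word (MMP1, DDAH1, EPHA1, AKT3, VDAC2, INSIG1, MAPK6, TMEM65 and ERLIN2), as do PERP, NQO1 and TGFA, so these are candidates for it; 1 of the 3 words or more is in 75.6% of the called lower genes, in 44.2% of genes of matched length and in 4 of the 8 searched among the 10 highest. An effect of plectin loss is not excluded for them, nor for the 43 genes without a lead word, MMP10, SERPINE1 and LAMA3 among them. In the direct comparison ATGGCAT (lower in JUP knockdown) and GGAATAA (higher) ranked 1 on the other chromosomes (permutation p = 0.000999 each). There 34.1% of 205 called lower genes carried ATGGCAT against 11.5% of other genes, and 24.8% of 129 higher genes carried GGAATAA against 13.8%. Its higher genes named by fold carry a PLEC lead word, all but HMOX1 and SERPINE1. Of its lower ones, SCML1, MSI2 and P2RY1 carry a JUP lead word. Off-target silencing may add to these calls too.

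The third pattern is the calls of either knockdown against the scrambled libraries, which principal component 1 and the mitochondrial share set partly apart. Of the 35 splits of 8 libraries, 3 gave as many calls as the real 290 for PLEC knockdown, so chance cannot be excluded for that count; the highest other, 603, put PLEC knockdown replicate 1 with scrambled replicates 1, 2 and 3, and 362 came from scrambled replicates 1 and 2 with PLEC knockdown replicates 1 and 2, which points to a structure of the samples. For JUP knockdown 1 of 35 gave as many as the real 276 (highest other 40). For the direct comparison 1 of 35 gave as many as the real 769 (highest other 1). That 1 is the real split itself, the fewest that 35 splits can give, so chance is argued against for both but not excluded. Genes picked with 2 PLEC knockdown libraries against the scrambled ones went the same way in the other 2 against JUP knockdown in 87.2% on average (78.2 to 91.7% over the 6 splits), and for JUP knockdown against PLEC knockdown in 89.5% (86.5 to 90.9%), against 54% and 61.7% of all genes. Differences on the scrambled side alone gave 46.3% for PLEC and 45.6% for JUP knockdown in simulation, which argues against these as the whole cause. The simulation drew each gene independently, without the structure of the samples seen in principal component 1. Its bar was also set after seeing the data, so the scrambled side is not excluded. Differences between libraries may still set how many genes pass.

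For the correlation of the knockdowns, the mean r of 0.0818 with split controls lay above the highest of 20 simulated means, 0.026. It also lay above the highest with a tie between same-numbered libraries, 0.0187. By the prediction, the shared scrambled libraries are then not its whole cause. The simulations drew each gene independently, though real genes vary together (estimated correlation 0.941 among mitochondrial-encoded transcripts in JUP knockdown), so the simulated range may be too narrow. Single splits ran from -0.0167 to 0.128, and the shared libraries cannot be excluded as the cause.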

How the results depend on the processing

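Here the fit without the 3 libraries of highest mitochondrial share, its list tests with an estimated correlation and the fit with that share as a covariate were chosen after seeing the data. The JUP log2 fold change in JUP knockdown lay between -4.25 and -3.97 and that of PLEC in PLEC knockdown between -1.98 and -1.85 over the 12 fits that left out 1 library, and both passed in every setting run. No called gene changed sign in any setting. Other scaling factors and no filter kept every count within 1.5 times, for example 66 higher and 211 lower in JUP knockdown with relative log expression factors. The number of passing genes is what depends on the processing, with the cause not tested except where stated.

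DESeq2 called 516 higher and 651 lower in JUP knockdown (55.8% lower against 76.8% by edgeR), 334 and 476 in PLEC knockdown, 578 and 719 in the direct comparison and 55 and 71 in both knockdowns; it shared 268 of the 276, 283 of the 290 and 755 of the 769 edgeR calls. The stricter filter, which tests fewer genes, gave 155 higher in JUP knockdown, r of 0.420 and 15 and 25 in both. Voom with quality weights gave 189 and 370 in JUP knockdown, 616 and 781 in the direct comparison and 20 and 35 in both. Fits of only 8 libraries gave 22 and 83, 5 and 27, 588 higher in the direct comparison, and 1 and 1 in both. Against a 1.5-fold change glmTreat, by its construction, gave 0 and 1 for JUP knockdown, 0 and 1 for PLEC knockdown and 1 and 1 for the direct comparison; against no change, 3795, 2718 and 3248 genes had an unadjusted p under 0.05.

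Without the 3 high-mitochondrial libraries there were 11 and 28 calls in JUP knockdown, 57 higher in PLEC knockdown, 561 higher in the direct comparison, r of 0.547 and 2 lower in both. It shared 31, 147 and 725 of the edgeR calls. The mitochondrial-encoded list reversed, with camera adjusted p = 0.675 (0.897 with an estimated correlation) for JUP knockdown and 0.00159 for the direct comparison; the removed libraries were picked on that share. Of 117 list results that fit ended 5 camera calls and added 12, among them, in the lower direction, hypoxia genes in PLEC knockdown (camera adjusted p = 0.00017), p53 targets in the direct comparison (0.00073) and inflammatory genes in JUP (0.0131) and PLEC knockdown (0.031); with an estimated correlation it had no call, and these p were 0.619, 0.310, 0.538 and 0.765. With the share as a covariate there were 10 and 58 in JUP knockdown, 63 higher in PLEC knockdown, 542 higher in the direct comparison and 1 lower in both.

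Leaving out 1 library gave 0 to 1035 higher and 19 to 1021 lower in JUP knockdown, 9 to 180 and 45 to 352 in PLEC knockdown, 133 to 417 and 177 to 575 in the direct comparison, 0 to 69 and 0 to 111 in both, and r of 0.416 to 0.605. The 0 and the lowest JUP count came without JUP knockdown replicate 1 and the highest without scrambled replicate 4.

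The replicate numbers were not taken as pairs, since not every correlation between same-numbered libraries was over 0.1, an arbitrary bar. They were 0.0103 to 0.15, all 12 above 0 and 4 above 0.1. Of 12 libraries 9 correlated best with their own number, a hint of a tie from the data that the main fit leaves out. The deposited columns give the scrambled libraries other numbers than the titles used here. With the number as a block there were 373 and 492 calls in JUP knockdown, 237 and 374 in PLEC knockdown, 524 higher in the direct comparison and 26 and 56 in both. With all libraries camera called 22 of the 117; the estimated correlation ended all 22, fry 20, and the block added 8. No fit at a lower depth was run; in simulation at these depths edgeR missed part of the 1.25-fold changes.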

Other observations

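The genes named here were chosen after their values were seen, as was the set of calls without a lead word. Called lower in both knockdowns were INSIG1 (log2 fold change -0.36 in JUP and -0.64 in PLEC knockdown), the kinase gene MAPK6 (-0.54 and -0.59, with 6 pseudogenes of its name), FAM3C (-0.35 and -0.57), the protease inhibitor SERPINB1 (-0.40 and -0.30), NABP1 (-0.41 and -0.33) and TM4SF1 (-0.22 and -0.23). Called higher in both were ARL6IP1 (0.23 and 0.30), the ubiquitin ligase subunit RNF7 (0.31 and 0.28) and the microtubule end-binding gene MAPRE1 (0.19 and 0.18). INSIG1 carries the JUP lead word ATGGCAT and the PLEC lead word GGAATAA, and MAPK6 the PLEC lead words GGAATAA and GGAGAAA, so they may be off-target in those knockdowns. These genes share their scrambled libraries, so part of the overlap may come from those: the mean r with split controls was 0.0818. For higher genes the word chosen on odd-numbered chromosomes was GCGATTA in both knockdowns. On the others its permutation p was 0.025 in JUP and 0.00799 in PLEC knockdown, but it ranked 325 and 120 of 16384. Of called higher genes there, 1 of 24 and 1 of 41 carried it. Over all genes its z score was 5.54 and 4.88, and 0.205 in the direct comparison. A difference on the shared scrambled side would give this pattern, which was not tested for the word. GRB10, an adaptor of insulin receptor signalling, was the 1 gene called in opposite directions, higher in JUP knockdown (0.24) and lower in PLEC knockdown (-0.31), and the direct difference was 0.55 (SE 0.05, edgeR adjusted p = 6.0e-05).

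Each knockdown lowered a gene of the RNA interference machinery, 1 of 15 on that list in each. AGO2, the slicing Argonaute, fell in JUP knockdown (-0.51, SE 0.06, edgeR adjusted p = 0.0012) and had -0.13 in PLEC knockdown, with a direct difference of -0.38 (edgeR adjusted p = 0.0041). DICER1 fell in PLEC knockdown (-0.34, SE 0.07, edgeR adjusted p = 0.0273) and had -0.06 in JUP knockdown, with a direct difference of 0.28 (edgeR adjusted p = 0.036). Without the 3 high-mitochondrial libraries 1 member of the list fell in JUP knockdown and 0 in PLEC knockdown, where DICER1 was thus not called. In the 3′ untranslated region AGO2 carries the JUP lead word ATGGCAT and also the PLEC lead words GGAGAAA and GATGATC, although it was not called in PLEC knockdown (edgeR adjusted p = 0.332); DICER1 carries GGAGAAA. Among searched calls without a lead word of the knockdown, 88 were lower and 60 higher in JUP knockdown (59.5% lower), and 43 lower and 60 higher in PLEC knockdown (41.7% lower). The words were picked for their tie to lower expression in these data, so dropping their carriers lowers that share partly by construction. Genes matched to the lower calls in length carry a lead word in 26% for JUP and 44.2% for PLEC knockdown. The shares thus do not tell how many lower calls are off-target. Of 33 type I interferon genes edgeR called 0 in either knockdown, with 1 higher and 4 lower at an unadjusted p under 0.05 in JUP and 1 and 3 in PLEC knockdown, and 0 and 1 by DESeq2.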
